A study of Mus musculus with 7 samples.

How the data were processed

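RNA was measured by sequencing in 7 libraries of mouse T follicular helper (Tfh) cells, the CD4 T cells that enter B cell follicles and help B cells. Per the labels' protocols, CD4 T cells carrying the transgenic Smarta T cell receptor, either wild type or lacking Tcf1 and Lef1 (the products of Tcf7 and Lef1), were transferred into recipients of a different CD45 allele, the recipients were immunised in the footpad with a GP61-KLH conjugate, and 5 days later the transferred CD4+ CXCR5+ PD1+ cells were sorted from draining lymph nodes. The titles place 4 libraries in the control group and 3 in the knockout group. The labels do not say whether libraries of a group came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical.

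The deposited values are raw counts of reads per gene, 1 column per library, for 49585 mouse Ensembl gene identifiers, and every column was used. The submitters' processing notes name CASAVA 1.8, STAR 2.7.0, Subread and DESeq2 and the mm10 genome build, without a role, order or setting for any of them. The annotation release, the strand setting and the handling of read pairs are not given in the sources used here. In the deposited counts 62.8% to 75.1% of the non-zero values of a library were even and a value of 2 was more frequent than a value of 1 in every library, so both ends of a read pair appear to have been counted; a count is then not an independent molecule, and counting-error limits are too narrow. The library labelled knockout 1 stood apart, with 3899 genes at 2 counts against 904 to 1232 in the other 6 libraries, and 18125 genes with a count against 13391 to 15685. Totals ran from 36821490 to 45133694 counts per library. Genes without counts were kept in the table, 26998 of which held no count in any library. A limit of 3 counts corresponds to 0.0665 to 0.0815 CPM (counts scaled to the library total), depending on the library, and covers counting error alone.

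Gene symbols, biotypes and coordinates were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the identifiers, 49326 (99.5%) matched without their version suffix, and 259 did not. Symbols shared by several identifiers were kept apart under the identifier. Because strand use is not stated, genes that overlap another gene cannot be separated from it, and genes with close copies share reads with them. Lef1 (with Gm43352), Cxcr5 (with Bcl9l) and Ctsw (with Fibp) are among the genes named below that overlap another.

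Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 12202. Scaling used TMM factors, and the genotypes were compared with edgeR 4.0.16 by the robust quasi-likelihood F-test with genotype as the single term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors were the log2 fold change divided by the square root of F. Levels are CPM of the TMM-scaled libraries, given as mean ± SD. Fitted fold changes of genes nearly absent from 1 group depend on the small count that edgeR adds, so their levels are given with them. Library measures were compared by exact two-sided permutation tests over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 8 such measures. Analyses ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with matplotlib 3.10.9.

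Gene lists were fixed before the data were examined, 29 in number: Tfh identity, B cell help and SLAM family, naive and memory-like T cell, Wnt and beta-catenin targets, TCF/LEF family and partners, Th1, cytotoxic and CD8 lineage, Treg, Th2, Th17, coinhibitory receptors, costimulation and TNF receptor family, TCR signal induced, migration and chemokine receptors, cell cycle, survival and apoptosis, interferon response, glycolysis, cholesterol and fatty acid synthesis, IL-2, IL-7 and gamma-chain cytokine signalling, T cell core, markers of B cells, plasma cells, myeloid and dendritic cells, NK and innate lymphoid cells, stromal and endothelial cells, and erythroid cells and platelets, stress and dissociation, and mitochondrially encoded. Tcf7 and Lef1 were left out of every list. Each list was tested with limma's camera on log2 CPM (prior count 2, preset correlation between genes 0.01) and adjusted over the 29 lists; camera compares a list with all other genes. Camera with a correlation estimated from the data, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone.

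The genes named were set by a rule fixed before the data were examined: Tcf7 and Lef1; the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, leaving out predicted models and provisional Rik names, pseudogenes and receptor V, D and J segments; 20 genes named whatever their result; and up to 5 members with the smallest p from each list. Named outside the rule, after their values were seen, are Cd7, 2310057M21Rik and, as members past the threshold adjusted over the list alone, Rrm2, Nsg2, S1pr2 and Ccr10, besides genes said to be so. Some genes that the rule selects are not reported here.

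The alternatives fixed before the data were examined were RLE, upper-quartile and library-total scaling, no low-count filter, a filter at a mean of 5 CPM, DESeq2, limma-voom with quality weights, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, and the other list tests. Alternatives added after seeing the data were counts halved, the fit without robust estimation, and fits with only controls 1 and 2 or only controls 3 and 4. The fits were tested on counts simulated for the 12202 genes with 50 changed genes at each fold, drawn from genes with a mean of at least 5 CPM. A further set of more abundant genes was raised 2-fold to test camera. Those genes can be among the calls but are not in the recovery rates, which do not cover rarer genes. The counts were negative binomial, with the dispersion that edgeR estimated for each gene, a setting that may favour edgeR. Loss particular to a library, counting of both read ends and correlation between genes were not simulated. The rates below therefore need not hold for the real libraries. edgeR recovered 12% of simulated 2-fold, 46% of 4-fold, 52% of 8-fold and 82% of 16-fold changes, with 2 false calls among 101 and 0 calls where no change was simulated. DESeq2 recovered 26%, 62%, 76% and 96% of the same changes, with 106 false calls among 246 (43.1%) and 64 calls where no change was simulated. The limma-voom fit recovered 6%, 24%, 28% and 48%, with 0 false calls among 57. The outlier check covered the 4 control libraries only, and groups of 3 were not tested.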

Results

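Expression was measured in sorted donor Tfh cells from mouse lymph nodes 5 days after immunisation, in 4 control libraries and 3 libraries labelled knockout for Tcf7 and Lef1. These genes encode the transcription factors TCF1 and LEF1. Library totals ran from 36821490 to 45133694 counts in controls and from 39781443 to 43838602 in the libraries labelled knockout. The question set by the design is which genes differ between Tfh cells with and without these factors after vaccination.

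Lef1 was lower and Tcf7 was higher in every library labelled knockout than in any control. Lef1 (chromosome 3, 131110471 to 131224356, GRCm38) stood at 221 ± 22.9 CPM in controls (SD, n = 4) and at 120 ± 28.4 CPM in the libraries labelled knockout (n = 3). Its log2 fold change of -0.89 ± 0.21 (SE) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.150). Tcf7 (chromosome 11, 52252371 to 52283014) stood at 1551 ± 174 CPM in controls and at 2172 ± 322 CPM in the libraries labelled knockout. Its log2 fold change was 0.49 ± 0.13 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.226). The Tcf7 count therefore goes against the label. A whole-gene count includes reads from exons outside a deletion. The labels do not say which exons were removed, so the count cannot check the deletion. Under DESeq2 both genes passed the threshold, Tcf7 upward and Lef1 downward, with adjusted p of 0.0191 and 0.00445.

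**Figure D1:**
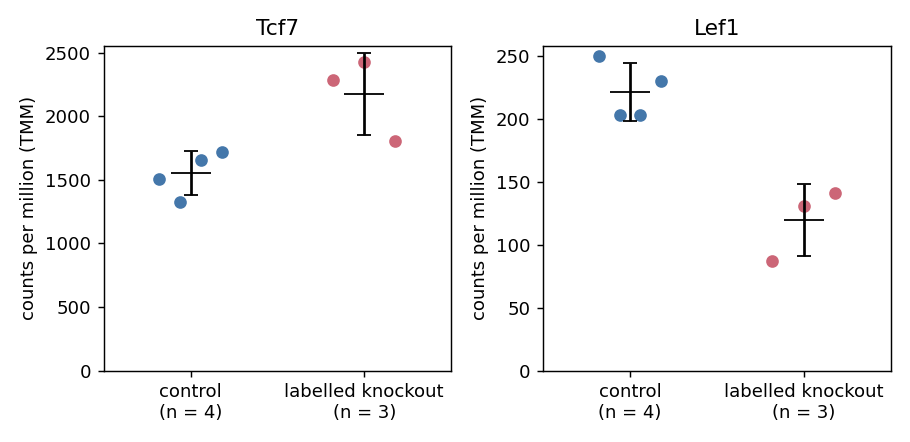
Tcf7 and Lef1 in CPM (vertical axes, TMM-scaled, from 0) in each control library (blue) and each library labelled knockout (red), with the mean and SD of each group in black. All 3 libraries labelled knockout lie above the controls for Tcf7 (1808 to 2423 against 1326 to 1718) and below them for Lef1 (87.4 to 141 against 203 to 250).

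The share of counts from the transgenic receptor differed between the groups by less than the spread between libraries. Trbv13-1, the V beta segment of the Smarta receptor, took 99.1 ± 0.062% of V beta counts in controls (SD, n = 4) and 99.0 ± 0.415% in the libraries labelled knockout (n = 3; exact permutation test, two-sided p = 0.771, adjusted 0.83). The Trav14 family took 97.8 ± 0.580% and 97.7 ± 0.856% of V alpha counts (exact permutation p = 0.83, adjusted 0.83).

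Between the groups 52 of 12202 genes changed in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05). In the libraries labelled knockout 30 were higher and 22 lower, and 46 of them changed by at least 2-fold (25 higher, 21 lower). Cd7, a surface glycoprotein of T and NK cells named outside the rule for its smallest p, rose from 63.8 ± 10.4 CPM (SD, n = 4) to 375 ± 21.8 CPM (n = 3). Its log2 fold change was 2.55 ± 0.18 (SE), with an edgeR adjusted p of 0.00328. Il6st, the signalling subunit of the IL-6 receptor, fell from 242 ± 24.7 to 64.2 ± 8.17 CPM (log2 -1.92 ± 0.18, edgeR adjusted p = 0.0120). Gpr183, the oxysterol receptor also known as EBI2, fell from 571 ± 155 to 76.1 ± 18.1 CPM (log2 -2.91 ± 0.29, edgeR adjusted p = 0.0121). Slamf6, a SLAM family receptor, fell from 1042 ± 171 to 469 ± 70.3 CPM (log2 -1.15 ± 0.16).

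Under the naming rule the largest rises were in Pltp, Dennd5a, Matn2, Plac8, Fgl2, Capn3, Ccl5, Csf1, Cdk5rap1 and Ube2l6. Ccl5, a chemokine, rose from 11.8 ± 6.13 to 128 ± 38.5 CPM (log2 3.43 ± 0.45, SE). Csf1, the macrophage colony-stimulating factor, rose from 10.6 ± 3.05 to 93.1 ± 15.4 CPM (log2 3.14 ± 0.36). Fgl2, a fibrinogen-like protein secreted by regulatory T cells, rose from 7.79 ± 3.86 to 93.4 ± 11.2 CPM. Pltp and Dennd5a were close to absent in controls, with 14 and 33 counts over the 4 libraries. They stood at 23.9 ± 9.89 and 23.5 ± 4.24 CPM in the libraries labelled knockout. By the same rule the largest falls were in Aplp1, Cebpb, Gna14, Ramp3, Myb, Ppic, Padi4, Ntrk3, Smtn and Adk. Aplp1, Cebpb and Gna14 kept 16, 12 and 16 counts over the 3 libraries labelled knockout, against 27.2 ± 6.51, 16.4 ± 6.39 and 20.4 ± 9.31 CPM in controls. Myb, a transcription factor, fell from 42.4 ± 14.3 to 0.587 ± 0.185 CPM, and Smtn from 270 ± 54.1 to 6.88 ± 7.36 CPM. Adk, adenosine kinase, fell from 132 ± 21.8 to 16.9 ± 5.15 CPM. The 20 genes had adjusted p between 0.0121 and 0.0433 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, Pltp overlaps Ctsa, Matn2 overlaps 9430069I07Rik, Capn3 overlaps Ganc and Cebpb overlaps Tmem189. Ramp3 overlaps Gm11978, Myb overlaps Gm26577, and Smtn overlaps Gm11946 and Gm11947. Their counts cannot be separated from those of the overlapping gene. The protein-coding gene 2310057M21Rik, which the rule leaves out for its provisional name, also fell, from 26.3 ± 10.4 to 0.430 ± 0.0610 CPM (log2 -5.93 ± 0.85).

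**Figure D2:**
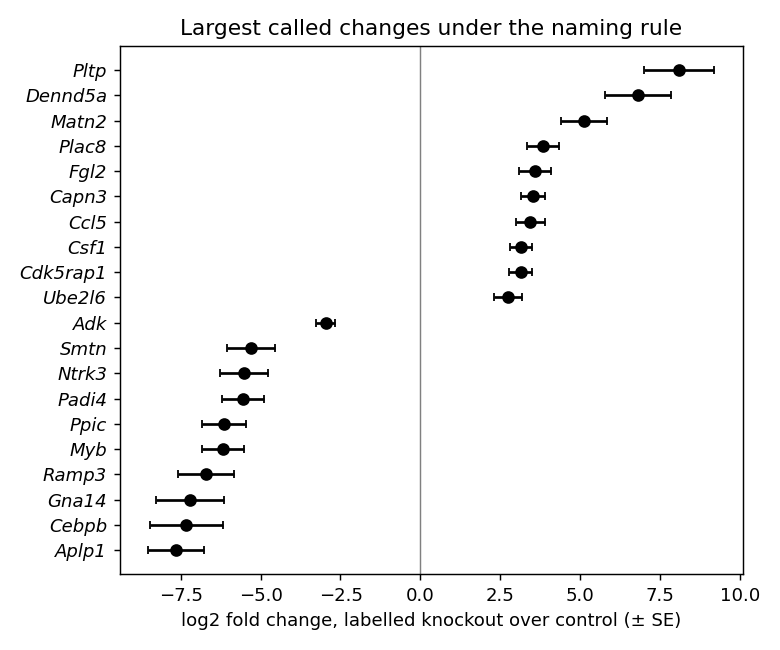
Log2 fold change, libraries labelled knockout over control (horizontal axis), with its standard error, for the 10 largest called rises and the 10 largest called falls under the naming rule, which leaves out 2310057M21Rik (-5.93). Estimates run from -7.64 for Aplp1, with 16 counts over the 3 libraries labelled knockout, to 8.09 for Pltp, with 14 counts over the 4 controls.

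The count of called genes rested on all 7 libraries. edgeR's quasi-likelihood test called 1, 24, 2 and 14 genes without control 1, 2, 3 and 4. It called 11, 19 and 15 genes without the library labelled knockout 1, 2 and 3. Of the 52 genes, Cd7 alone was called in all 7 of these fits, 6 genes in at least 5, and 24 in none. Among the 24 are Slamf6, Pltp, Dennd5a, Fgl2, Cebpb, Gna14, Ramp3 and Cst7. With upper-quartile scaling 23 genes were higher and 27 lower, and with library totals 24 and 25, against 30 and 22 with TMM. With limma-voom 32 were higher and 2 lower. Pearson correlations of log2 CPM were 0.778 to 0.899 within controls, 0.768 to 0.778 within the libraries labelled knockout and 0.739 to 0.820 between groups. Each library labelled knockout correlated more closely with controls 3 and 4 than with the others of its group. On the first principal component (24.2% of the variance) the groups did not overlap, with controls at -134 to -23.6 and the libraries labelled knockout at 60.6 to 110. The libraries also differed in how many genes they lost. Of genes averaging 10 to 20 CPM, 8.07%, 18.1%, 1.03% and 1.30% lay below 1/10 of their mean in controls 1 to 4. The libraries labelled knockout lost 15.7%, 19.6% and 15.5% (exact permutation p = 0.114, adjusted 0.229, of the group means).

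**Figure D3:**
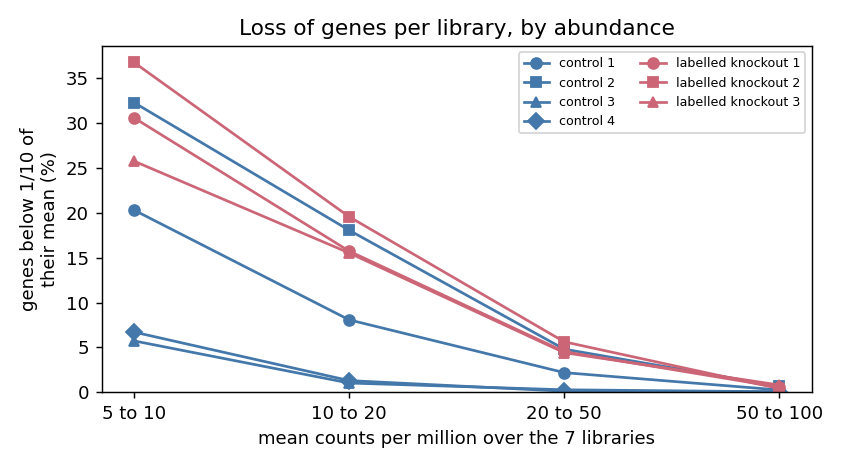
Percentage of genes lying below 1/10 of their mean over the 7 libraries (vertical axis, from 0), by mean CPM (horizontal axis), for each control library (blue) and each library labelled knockout (red). At 10 to 20 CPM, controls 3 and 4 lost 1.03% and 1.30% of genes, control 2 lost 18.1%, and the libraries labelled knockout lost 15.5% to 19.6%.

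Genes of the Tfh programme lay on both sides of 0. Of the 34 members of the Tfh identity list, 0 rose and 2 fell (Il6st and Slamf6) over all genes tested. Adjusted over the list alone 4 were higher (Cxcr5, Il21r, Nfatc1 and Tbc1d4) and 5 lower (Il4, Slamf6, Il6st, Cd200 and Izumo1r). The list as a whole was not called in a single direction (camera adjusted p = 0.840, median log2 fold change -0.05). Camera does not test for members that move both ways. The mixed form of fry, which counts changes either way, gave an adjusted p of 6.36e-06. It does not compare the list with other genes and also passed lists such as glycolysis (adjusted p = 0.0219). The mixed test therefore does not single out the Tfh list. Cxcr5, which with Pdcd1 defined the sorting gate, stood at 859 ± 70.9 CPM in controls (SD, n = 4) and 1378 ± 219 CPM in the libraries labelled knockout (n = 3; edgeR quasi-likelihood adjusted p = 0.0959). Pdcd1 stood at 998 ± 129 and 925 ± 27.4 CPM (adjusted p = 0.892). Bcl6, the lineage-defining repressor of Tfh cells, stood at 384 ± 92.1 and 467 ± 57.3 CPM (edgeR adjusted p = 0.737). Icos stood at 285 ± 52.6 and 360 ± 21.4 CPM (edgeR adjusted p = 0.543), and Il21 at 113 ± 46.2 and 233 ± 122 CPM (adjusted p = 0.399). Il4 stood at 207 ± 31.6 and 115 ± 20.5 CPM (edgeR adjusted p = 0.156), and Cd200 at 319 ± 42.8 and 142 ± 31.3 CPM (adjusted p = 0.0595). Cd40lg, Sh2d1a, Maf and Ascl2 gave log2 fold changes of 0.35 ± 0.21, -0.00062 ± 0.17, 0.29 ± 0.18 and -1.08 ± 0.74 (SE), with edgeR adjusted p between 0.661 and 0.9998.

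By camera 8 of the 29 lists were called, and with an estimated correlation 0 were. The cell cycle, cytotoxic and CD8 lineage, and erythroid and platelet lists were called in all 18 alternative camera fits run with the preset correlation. The other 5 lists were called in 6 to 14 of these 18 fits, with adjusted p up to 0.327, and each lost the call when certain single libraries were left out. The naive and memory-like list lost it without control 2 or any 1 library labelled knockout. Th1 lost it without control 1 or 3 or any 1 library labelled knockout. Treg lost it without control 2, 3 or 4 or the library labelled knockout 1 or 3. Costimulation lost it without control 3 or the library labelled knockout 3. Mitochondrially encoded lost it without control 1, 2 or 3 or the library labelled knockout 1 or 3.

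The naive and memory-like T cell list was lower (camera adjusted p = 0.0481, and adjusted p = 0.287 with an estimated correlation). Of its 23 members 2, Myb among them, fell over all genes and 0 rose. When adjusted over the list alone 6 were lower and 2 higher. The lower members by that count included Myb, Ccr7, S1pr1, Dapl1 and Nsg2. Ccr7, the lymph node homing receptor, stood at 174 ± 55.2 and 57.6 ± 20.4 CPM (edgeR quasi-likelihood adjusted p = 0.143), and Dapl1 at 31.6 ± 15.0 and 1.13 ± 0.815 CPM (adjusted p = 0.0694).

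The cell cycle list was lower (camera adjusted p = 5.57e-07, and adjusted p = 0.287 with an estimated correlation). Of its 33 members 32 lay on the lower side, with a median log2 fold change of -0.74. No member was called over all genes. Adjusted over the list alone 6 were lower (Ccne1, Aurka, Cenpa, Tyms, Rrm2 and Uhrf1) and 0 higher. Uhrf1, a maintenance methylation factor, stood at 66.9 ± 19.3 CPM in controls (SD, n = 4) and 20.98 ± 2.65 CPM in the libraries labelled knockout (n = 3; edgeR adjusted p = 0.128). Tyms, thymidylate synthase, stood at 90.5 ± 17.4 and 40.2 ± 6.65 CPM (adjusted p = 0.148).

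Lists of other T cell lineages lay on the higher side. The cytotoxic and CD8 lineage list was higher (camera adjusted p = 4.14e-06, and adjusted p = 0.287 with an estimated correlation). It was not called by fry (adjusted p = 0.0971). Of its 19 members 18 had positive fold changes and 2, Ccl5 and Cst7, rose over all genes. Fasl and Ctsw were higher too when adjusted over the list alone. Ctsw, a protease of cytotoxic cells, stood at 35.8 ± 15.96 and 155 ± 27.4 CPM (edgeR quasi-likelihood adjusted p = 0.0819). Cd8a stood at 11.1 ± 6.78 and 20.7 ± 24.9 CPM (edgeR adjusted p = 0.881), and its log2 fold change turned to -0.80 without the library labelled knockout 3. Gzmb was below the expression filter, with 103 counts over the 4 controls and 16 over the 3 libraries labelled knockout.

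The Treg list was higher (camera adjusted p = 0.0433, and adjusted p = 0.287 with an estimated correlation). Of its 17 members 1 rose over all genes: Nt5e, the ecto-nucleotidase CD73, from 294 ± 43.1 to 696 ± 7.71 CPM (edgeR adjusted p = 0.0121). Foxp3, Ctla4, Itgae and Il2rb were also higher, and Capg and Izumo1r lower, when adjusted over the list alone. Ctla4 stood at 39.0 ± 10.9 and 109 ± 8.93 CPM (edgeR adjusted p = 0.0962) and Itgae at 2.56 ± 2.88 and 86.6 ± 21.9 CPM (adjusted p = 0.115). Foxp3, the Treg lineage factor, held 1690 of its 1702 counts in the libraries labelled knockout in the library labelled knockout 1, which also held more genes with a count (18125) than any other library. Its log2 fold change of 6.34 became -0.08 without that library.

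The Th1 list was higher (camera adjusted p = 0.0481, and adjusted p = 0.287 with an estimated correlation). Ccl5 was the 1 of its 19 members called over all genes. Adjusted over the list alone 2 were higher (Cxcr3 and Ccl5) and 2 lower (Il12rb1 and Cxcr6). Tbx21, the Th1 lineage factor, stood at 12.1 ± 14.1 and 41.0 ± 18.4 CPM (edgeR quasi-likelihood adjusted p = 0.766), and Ifng at 3.87 ± 3.35 and 15.2 ± 6.37 CPM (adjusted p = 0.775). The costimulation and TNF receptor family list was higher (camera adjusted p = 0.02495, and adjusted p = 0.287 with an estimated correlation). Of its 19 members 15 had positive fold changes and 0 were called by either count. Among coinhibitory receptors Lag3 rose from 332 ± 155 to 1638 ± 108 CPM (log2 2.30 ± 0.35, SE; edgeR adjusted p = 0.0387). Cd96 rose from 150 ± 8.13 to 390 ± 49.6 CPM (log2 1.38 ± 0.14, edgeR adjusted p = 0.0121). Ctla4 and Vsir were also higher, and Tigit lower, when adjusted over the list alone. The coinhibitory list was not called by camera (adjusted p = 0.107) but was called higher by fry (adjusted p = 0.0386). Prdm1, Id2 and Gata3 gave log2 fold changes of 1.71 ± 2.37, 0.16 ± 0.38 and 0.22 ± 0.24 (edgeR adjusted p = 0.924, 0.969 and 0.887). They turned to -0.33 for Prdm1 without the library labelled knockout 2, to -0.05 and -0.03 for Id2 without control 3 and without the library labelled knockout 3, and to -0.02 for Gata3 without the library labelled knockout 3.

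Receptors that direct migration lay on both sides of 0. Of 26 members of the migration list 2, Gpr183 among them, fell over all genes and 0 rose. Adjusted over the list alone 7 were higher (Cxcr5, S1pr2, Itgae, Cxcr3, Ccr4, Ccr6 and Ccr8) and 6 lower (Ccr7, S1pr1, Gpr183, Ccr10 and Cxcr6 among them). The list was not called in a single direction (camera adjusted p = 0.932). Ccr8 stood at 3.44 ± 3.24 CPM in controls and 145 ± 9.32 CPM in the libraries labelled knockout (log2 5.40 ± 0.93, SE; edgeR quasi-likelihood adjusted p = 0.0633). Ccr6 stood at 6.18 ± 7.01 and 98.1 ± 26.0 CPM (adjusted p = 0.187).

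Among markers of other cells and of RNA quality, 2 lists were called. The erythroid and platelet list was higher (camera adjusted p = 3.11e-05, and adjusted p = 0.287 with an estimated correlation), with 7 of 7 positive fold changes. No member was called over all genes, and 3 were adjusted over the list alone (Hba-a1, Hbb-bs and Hbb-bt). The globin genes, whose close copies share reads, took 0.00772 ± 0.00345% of counts in controls and 0.0240 ± 0.00475% in the libraries labelled knockout (exact permutation p = 0.0286, the smallest possible, adjusted 0.229). Ribosomal RNA took 1.63 ± 0.702% and 2.695 ± 0.254% of counts (exact permutation p = 0.0857, adjusted 0.229). The mitochondrially encoded list was higher (camera adjusted p = 0.0487, and adjusted p = 0.539 with an estimated correlation), with 0 of 15 members called by either count. The smallest p were those of the ribosomal RNAs mt-Rnr2 and mt-Rnr1. The lists of B cell, plasma cell, myeloid and dendritic cell, NK and innate lymphoid cell, and stromal and endothelial markers were not called (camera adjusted p = 0.899, 0.0960, 0.191, 0.350 and 0.888), and the last rests on 1 measured member. The NK and innate lymphoid list rests on 6 of its 18 members, and the myeloid and dendritic list on 11 of 22. Plasma cell markers were called higher without control 1 (camera adjusted p = 0.0391) and with the replicate number as a block (0.0387). The myeloid list was called higher at a mean of at least 5 CPM (0.0379), and the stromal list without the library labelled knockout 2 (0.0328).

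Camera did not call the remaining lists either, though fry called survival and apoptosis higher (fry adjusted p = 0.0361). The camera adjusted p was 0.0834 for Th17, 0.191 for Th2, 0.130 for interferon response, 0.0960 for survival and apoptosis, 0.386 for TCR signal induced, 0.664 for B cell help and SLAM family, 0.932 for Wnt and beta-catenin targets, 0.841 for glycolysis, and 0.899 for T cell core and for stress and dissociation. It was 0.840 for TCF/LEF family and partners, for IL-2, IL-7 and gamma-chain cytokine signalling, and for cholesterol and fatty acid synthesis. The Wnt list rests on 5 of its 16 members, Th17 on 8 of 15 and Th2 on 7 of 15. The other members were below the expression filter, so these tests say nothing of them. The interferon response list was called higher without the library labelled knockout 1 (camera adjusted p = 0.000758) and without control 3 (0.0127). The Th17 list was called higher without control 3 (0.0167) and without the library labelled knockout 3 (0.0281). Ifi208 of the interferon response list rose from 84.8 ± 12.7 to 327 ± 77.9 CPM (log2 1.95 ± 0.21, SE; edgeR quasi-likelihood adjusted p = 0.0121). Axin2, a Wnt target, stood at 13.2 ± 9.01 and 1.59 ± 1.05 CPM (adjusted p = 0.419). Some genes, such as Cxcr5 and Ccr7, belong to more than 1 list, so the lists are not independent of each other.

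**Figure D4:**
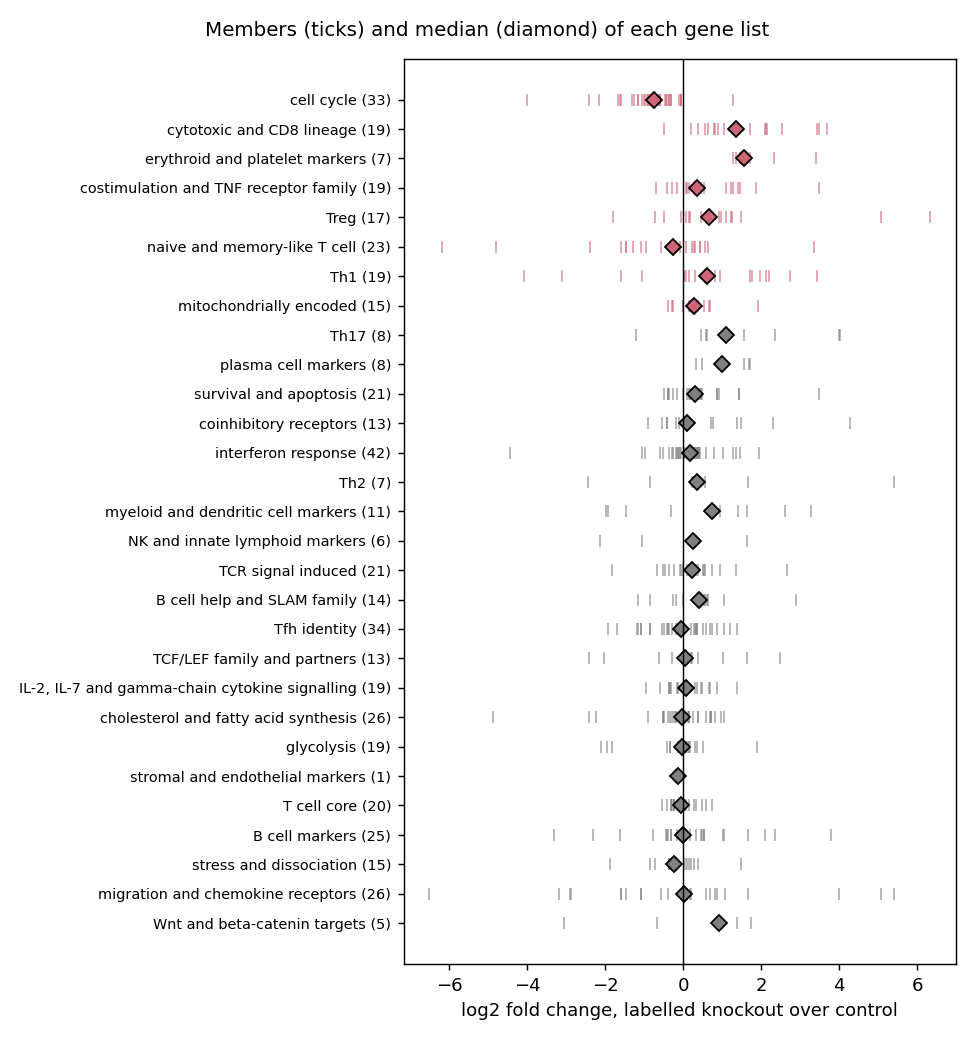
Log2 fold change, libraries labelled knockout over control (horizontal axis), of the members (ticks) of each of the 29 gene lists, with the list median as a diamond and the number of measured members in parentheses; red marks the 8 lists called by camera with the preset correlation. The cell cycle median lies at -0.74 and that of the cytotoxic and CD8 lineage list at 1.34.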

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

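The tests below on Tcf7, the cell cycle list and genes close to absent were chosen after the values were seen; the counts over other splits of the libraries were not.

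By the share of splits, 0.0286 and the smallest that 35 splits can give, chance can be excluded at 0.05 for both gene counts. Of the 35 splits of the 7 libraries into 4 and 3, only the real one gave as many called genes (52, highest other 0). The same held for genes called with a 2-fold change (46, highest other 0). Called lists were also most numerous in the real split (8, highest other 6), at the same share. Lists reached 6 in 2 other splits, controls 1, 2 and 3 against the rest, and control 4 with the libraries labelled knockout 1 and 3 against the rest. Both of these follow the genotype in part. Controls 1 and 3 with the library labelled knockout 2, against the rest, gave 4 lists. Camera with the preset correlation thus called lists with genotypes mixed on both sides. The share does not exclude chance for any 1 list. The list counts are those with the preset correlation, and with an estimated one 0 lists were called in the real split (4 at unadjusted p under 0.05).

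In 14 cases 1 control library lay far from the other 3, by the gap divided by the range, among 168 values tested, where chance flags about 1 in 20. Control 3 stood apart for Pltp (0.188 CPM, ratio 0.947), Il4 (160 CPM, 0.860), Tmem176b (7.15 CPM, 0.974), Blk (6.21 CPM, 0.979) and Rcan1 (18.1 CPM, 0.833). Control 2 stood apart for Maf (185 CPM, 0.831), Prdm1 (17.3 CPM, 0.992), Slamf6 (1295 CPM, 0.848) and Fcgr3 (11.7 CPM, 0.980). Control 4 stood apart for Cd8a (21.1 CPM, 0.842), Tbc1d4 (601 CPM, 0.846), Izumo1r (1102 CPM, 0.892) and mt-Rnr1 (268 CPM, 0.878), and control 1 for Ppic (53.1 CPM, 0.929).

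Tcf7 counts were higher, not lower, in the libraries labelled knockout. Control libraries carrying the wrong label would hold Lef1 at the control level, but the highest library labelled knockout held 0.694 of the lowest control's Lef1 CPM. Recipient cells are argued against by the V beta counts outside Trbv13-1, at most 1.44% in a library labelled knockout; this share says nothing of undeleted donor cells, which carry the same receptor. Undeleted donor cells mixed in could at most bring Tcf7 up to the control level. Tcf7 above that level was not called (edgeR quasi-likelihood adjusted p = 0.226, lowest library labelled knockout 1.05 times the highest control), so Tcf7 alone leaves them open. Cells with both genes intact would then also hold Lef1 at the control level. Lef1 stood at 120 ± 28.4 against 221 ± 22.9 CPM, though not called (edgeR adjusted p = 0.150). These values argue against cells with both genes intact as the whole cause. Transcripts that lack the deleted part and are still counted as Tcf7 remain open beside an effect of the genotype on the gene's own transcription: the log2 fold change of 0.49 comes from whole-gene counts, and no counts per exon were analysed here.

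Cell cycle genes were lower in the libraries labelled knockout, which also lost more low-abundance genes than controls 3 and 4. Loss by abundance as the whole cause is argued against by the list's median log2 fold change of -0.74, below the 2.5 percent point of 10000 random lists matched on mean expression (-0.14) and below the lowest of them (-0.39). The 11 members above 100 CPM had a median of -0.36 and the rarer ones -0.92, so loss may still add to the size. Cell cycle genes that vary together between libraries whatever the genotype cannot be told apart from an effect of the genotype, because the tests differ. Camera with an estimated correlation gave an adjusted p of 0.287 (0.0251 before adjustment), while fry, which does not compare the list with other genes, gave 0.0343 (0.00473 before). The mean log2(CPM + 1) of the list was 4.70 to 5.35 in the libraries labelled knockout and 5.76 to 6.28 in controls, a separation that the lower side shows by chance in 1 of 35 splits. An effect of the genotype stays a hypothesis that the data leave untested.

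Several of the largest falls were in genes close to absent in all 3 libraries labelled knockout. A lower depth, taken as total counts, is argued against by the mean totals, 1.03 times those of the controls. Totals did not follow loss at 10 to 20 CPM. Control 2 had 45133694 counts and lost 18.1% of these genes, and control 4 had 37889679 and lost 1.30%. The totals therefore cannot show whether fewer molecules were sampled. There were 79 genes whose 3 libraries labelled knockout all lay below 1/10 of the control mean, against 6 to 53 in the other 34 splits. Only genes with a mean of at least 5 CPM were counted, both over the 7 libraries and over the 4 on the other side of the split. Rarer genes were left out. The 3 libraries labelled knockout and control 2 are the 4 that lost most genes at 10 to 20 CPM, so the 3 other splits that take 3 libraries from these 4 compare like with like. They gave 42 to 53 genes, and 79 exceeds the highest by more than 2 counting errors (67.6). That limit treats genes as independent and rests on 3 other splits. It cannot decide whether loss in single libraries is the whole cause. Loss may account for part of the 79 or for all of them, and genes are not independent of each other. The ratio of each count to that expected from independent loss was also looked at and is not used, since it was highest (33.6) where 0.596 genes were expected. An effect of the genotype stays a hypothesis, and a loss shared by the libraries labelled knockout was not tested.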

How the results depend on the processing

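Alternatives marked as added were chosen after seeing the data. The 52 called genes kept their sign in all 19 alternative fits, and the 8 called lists their direction in all 18. The groups did not overlap in any of the 52 genes, so a turn of sign was unlikely from the start. RLE scaling (52 genes, 46 by 2-fold) left the counts within 1.5 times. So did counts halved (added, 54 and 46) and the fit without robust estimation (added, 55 and 49). Without a low-count filter 119 genes were called (96 by 2-fold) and 4 lists. DESeq2 called 615 (486 by 2-fold, 226 higher and 389 lower), including all 52, with Tcf7 at 0.49 and Lef1 at -0.88. On counts simulated with edgeR's dispersions 43.1% of DESeq2's calls were false, a rate that need not hold for these libraries. limma-voom called 34 (29 by 2-fold; 32 higher, 2 lower; 28 shared), with the median log2 fold change of all genes at -0.083 against 0.043. At an adjusted p under 0.01, 1 gene remained. Camera with an estimated correlation called 0 lists (4 at unadjusted p under 0.05). Fry called 6: naive and memory-like, Treg, cell cycle, erythroid and platelet, survival and apoptosis, and coinhibitory receptors. The last 2 of these were not called by camera (fry adjusted p = 0.0361 and 0.0386). Fry did not call cytotoxic and CD8 lineage (adjusted p = 0.0971), Th1 (0.0673), costimulation (0.108) or mitochondrially encoded (0.153). At unadjusted p under 0.05 the edgeR test gave 1290 genes. Leaving out 1 library gave 1 to 24 genes, 1 to 24 by 2-fold, and 4 to 7 lists; with fewer libraries the test has less to work with, and 961 to 1407 genes still had an unadjusted p under 0.05. Controls 1 and 2 only (added) gave 4 genes, 4 by 2-fold and 3 lists, and controls 3 and 4 only (added) gave 2, 2 and 6. With the replicate number as a block edgeR called 0 genes (0 by 2-fold, 947 at unadjusted p under 0.05) and 6 lists. DESeq2 and limma-voom were not run with the block. The labels do not say what the numbers stand for. Same-numbered deviations correlated at 0.011 to 0.032 and other-numbered ones at -0.029 to 0.045. Of the libraries labelled knockout, 2 of 3 correlated best with their own number. Correlations this low do not settle whether the numbers pair the libraries. The block also leaves the test less to work with. Signs turned in 23 cases, in none of which a fit called the gene, and the cause was not tested: Sh2d1a (-0.00062) became 0.0043 with RLE and with DESeq2, 0.094 with limma-voom, 0.18 with controls 3 and 4 only, and -0.10 to 0.12 leaving out 1 library; Prickle1 -0.30 with limma-voom and -1.40 to 1.46 leaving out 1; Fcgr3 1.25 with limma-voom, 0.14 with the block, 1.82 with controls 3 and 4 only; Id2 -0.23, Fcrla 0.35 and Pecam1 0.0075 with controls 1 and 2 only. Leaving out 1 library, the ranges that crossed 0 were -0.33 to 2.28 for Prdm1, -0.052 to 0.52 for Id2, -0.019 to 0.42 for Gata3, -0.076 to 6.91 for Foxp3, -0.80 to 1.42 for Cd8a, -2.62 to 2.20 for Fcgr3 and -1.92 to 1.70 for Mzb1. In a library at most 0.0450% of genes above 100 CPM were lost, and up to 19.6% of genes at 10 to 20 CPM; how far this limits the calls was not tested.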

Other observations

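The tests in this part were chosen after the values were seen, and the genes below were too, unless named in the report. Adk fell by 2.96 ± 0.30 and Dck, deoxycytidine kinase, fell by 1.04 ± 0.15 on the log2 scale (Dck from 263 ± 22.1 CPM, SD, n = 4, to 128 ± 12.3 CPM, n = 3; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0312), while Nt5e, which makes extracellular adenosine, rose by 1.24 ± 0.14. Adjusted over the T cell core list alone Cd3e, Cd3g and Cd247 were higher and Trac and Trbc2 lower, and over all genes 0 of its 20 members were called. Cd3e stood at 816 ± 86.1 and 1366 ± 200.4 CPM (edgeR quasi-likelihood adjusted p = 0.0770) and Trac at 6295 ± 1113 and 4298 ± 320 CPM (adjusted p = 0.192). V alpha counts totalled 125313 ± 21978 in controls and 74879 ± 8651 in the libraries labelled knockout (exact permutation p = 0.0571, two-sided).

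Gpr18, a receptor of lymphocytes, rose from 93.7 ± 11.1 to 359 ± 51.6 CPM, with an edgeR quasi-likelihood adjusted p of 0.0107. Ly6a, Ly6e and H2-K1, members of families whose copies share reads, rose by 0.99 ± 0.16, 0.73 ± 0.09 and 0.69 ± 0.10 on the log2 scale. Dck, Ly6a, Ly6e and H2-K1 were called in none of the 7 edgeR fits that each leave out 1 library. A shared rise of MHC class I presentation genes was set up as a hypothesis from the rise of H2-K1 and tested on 16 other genes of that pathway. Of these 15 had positive fold changes, with a median of 0.26, and 0 were called. The 16 include H2-D1, H2-Q4, H2-Q6, H2-Q7, H2-T22 and H2-T23, class I genes that may share reads with H2-K1. The list is therefore not independent of the gene that prompted it. Camera gave p = 0.0709 with an estimated correlation and p = 0.00109 with the preset one, so a shared rise may be present but was not established.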
